A study of Mus musculus with 8 samples.

How the data were processed

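RNA of liver from 8 mice, 2 per combination of diet (ND or HFD) and feeding time (3 or 9 months), had been labelled with Cy3 and hybridised to Agilent whole-genome arrays, 1 array per animal. Per the labels the 2 arrays of a group hold RNA of separate mice, so the p-values measure the spread between animals together with that between arrays. Each array file deposited by the authors holds the output of Agilent Feature Extraction 10.7.1.1, as the submitters' processing notes name it. Per the file headers the processed signal is an intensity after background subtraction and spatial detrending, not scaled between arrays, and the median signals of spot and local background are intensity values with no correction. The deposited flags (well above background, outlier among replicate spots, non-uniform spot) are other values, 0 or 1 per spot. The deposited value table of the authors holds log2 values that, as tested on the files, rank each array exactly as its median signal does (Spearman's rho of 1) and have nearly equal distributions on all arrays (column medians of 7.14), so they are quantile-normalized median signals without background subtraction.

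Control spots (3671) were left out and 59305 spots were read. Spots with an outlier flag were dropped, the log2 processed signal was centred on each array's 75th percentile with a pseudocount of 0, and replicate spots of a probe were averaged, which gave 55603 of 55681 probes. A probe was kept when it was well above background on both arrays of at least 1 group (25801 probes; a probe counted as such when a share of 0.5 or more of its spots was). For each gene the kept probe with the highest mean over all arrays was used, which gave 20165 features, 12885 with a gene symbol and 7280 without. Gene names come from the array files, and 26056 probes matched 19752 symbols in a RefSeq table of assembly GRCm38.p6. The array annotation uses build mm9, so that table served for names only and no coordinates are given. Probes of close relatives, such as the Cyp2b genes, the metallothionein genes Mt1 and Mt2 or the pseudogene Serpina4-ps1, were not tested for cross-hybridisation.

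Genes were tested with limma 3.58.1 in R 4.3.3 with the package data.table, version 1.17.8,, by lmFit and eBayes with default moderation on the 4 group means, and called at a Benjamini-Hochberg adjusted p under 0.05. The fit of the 4 group means had 4 residual degrees of freedom and a prior of 2.33. Diet over both durations was tested in a second fit, to which these values do not apply. The contrasts were HFD versus ND at 3 months and at 9 months, their difference (interaction), 9 versus 3 months on each diet, and HFD versus ND over both durations with duration as a covariate. Gene lists (20 pathways and 13 sets of cell type markers) with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over all 33 lists, and again with an estimated correlation and with fry, which does not compare a list with other genes. Medians of lists include members near background at their fitted values. Counts adjusted over the list alone apply the Benjamini-Hochberg procedure to the members of 1 list. Correlations across genes carry no p-value, and chance values come from exchanging arrays between diets within each duration. Figures were drawn with Python 3.11.15 (matplotlib 3.10.9, numpy 2.4.6, pandas 2.3.3).

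Genes are named by a fixed rule. It takes the 8 largest rises and 8 largest falls for each comparison of diets and 5 of each for the other contrasts, among genes past the threshold with a proper symbol, signal above background in both groups and no overlap between the arrays compared. It adds up to 4 members with the smallest p of each list described for the comparisons of diets, a panel of 26 genes, and up to 3 genes per direction seen in 1 group only, which are given as bounds against the lowest signal well above background on the arrays of the other group. Where no gene passes, the 5 with the smallest p are named.

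The method was tested on simulated data with the noise of the 20165 measured features and a set of features changed at 9 months. At a log2 change of 1 the test found 3 of 67 changed features, at 2 it found 32 of 67 and at 3 it found 46 of 66, with 3 false calls among the unchanged. A list shifted by 1 was found, and 0 other lists were called. The noise was drawn independently for each feature, while in the data the estimated correlation within a list reached 0.772 (cholesterol synthesis). The simulation therefore cannot tell how often camera calls unshifted lists of correlated genes.

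Alternatives were quantile normalization, normexp background correction with an offset of 50 (on the median signal and median local background, since the mean signal was not among the columns used), the value table of the authors, no filter on dim probes, probes well above background on all arrays, a floor on dim values, the mean of all kept probes of a gene, moderation with trend and robust, array weights, a replicate block, the 4 compared arrays alone, no covariate, a 2-fold minimum, and leaving out each array in turn. Scaling to detected probes, leaving out the pair of arrays that stood apart, and all alternatives for the lists of the interaction were added after seeing the data. A group left with 1 array was assumed to vary like the other groups. Diet and slide cannot be told apart, so no slide term could be fitted for diet, and within a diet it changes nothing. MicroRNA values were not used here.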

Results

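Liver RNA from 8 male C57BL/6 mice was measured on 1-colour Agilent arrays, 1 array per animal. Mice ate a normal diet (ND, 4.8% fat) or a high-fat diet (HFD, 58% fat) for 3 or 9 months, which gave 4 groups of 2 animals. The 75th percentile of the intensity was 482 to 597 on the 4 ND arrays and 185 to 428 on the 4 HFD arrays. The value of 185 was that of HFD 9 months replicate 2, against 368 to 428 on the other HFD arrays. That array also had the lowest share of spots well above background (40.6%). Its scaled negative controls (-4.86) and E1A spike-in controls (6.01, against 3.14 to 4.75 on the other arrays) were the highest. Between 40.6% and 54.1% of the spots on an array were well above background. All ND arrays lay on 1 slide and all HFD arrays on the other. On each slide the 3-month arrays lay in row 1 and the 9-month arrays in row 2, so duration and row changed together. Spots of the same probe varied more on the HFD slide (SD of 0.116 to 0.174 on the log2 scale against 0.0624 to 0.0713). Diet and slide therefore cannot be told apart in any comparison of diets, and the number of arrays limits the precision of every value. The 2 arrays of a group correlated with r = 0.968 to 0.994 across genes, which are not independent replicates. Arrays of different diets correlated with r = 0.929 to 0.959. The first principal component, 46.6% of the variance, parted the ND from the HFD arrays, and the second, 21.1%, parted the 3-month from the 9-month arrays. Unless said otherwise, changes below are log2 fold changes ± SE from 1 limma fit of the 8 arrays (n = 2 animals per group). Those averaged over both durations come from a second fit with duration as a covariate. The contrasts, gene lists and rules for naming genes were fixed before the data were examined. Testing the gene lists for the interaction was not part of that plan.

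The comparison of diets at 3 months asked which liver genes differed early in high-fat feeding. The largest rises on HFD were those of Cyp2b13 (6.75 ± 1.18, 108-fold) and Cyp2b9 (5.1 ± 1.03). With 1 array left out they ran from 5.51 to 8.0 and from 4.33 to 5.86, each past the threshold in 4 of 8 cases. Both are cytochrome P450 genes of drug and steroid metabolism, normally low in male mouse liver. Rad51b, a DNA repair gene, rose by 4.17 ± 0.39, the organic anion transporter genes Slc22a29 and Slc22a27 by 4.07 ± 0.52 and 3.85 ± 0.61. Acot3, a peroxisomal acyl-CoA thioesterase, rose by 3.08 ± 0.43. Genes induced by inflammatory cytokines were among them: Ubd, a ubiquitin-like modifier, rose by 3.67 ± 0.35 and Gbp2, an interferon-inducible GTPase, by 3.02 ± 0.36. The largest falls were those of Serpina4-ps1, a serpin pseudogene (-5.39 ± 0.52), Pax2 (-5.16 ± 1.05), Krtap19-5 (-4.42 ± 0.54), Teddm2 (-4.2 ± 0.65), Bard1 (-4.11 ± 0.4), Olfr1350 (-4.04 ± 0.75), Pramel34 (-3.89 ± 0.46) and Smok3b (-3.8 ± 0.48). Of these, Pax2, Teddm2, Bard1 and Pramel34 have other probes on the array that were on average higher on HFD, by 0.47, 0.41, 0.70 and 0.59. Every gene named so far was higher, or lower, on both HFD arrays than on both ND arrays, which the rule for names requires. Some genes were near background in 1 group and give bounds only: Ttc39a, Stap1 and Fignl1 were at least 17.9-fold, 12.4-fold and 10.2-fold higher on HFD. Izumo1r, Ppargc1b (a coactivator of metabolic transcription) and Hyal6 were at least 17.8-fold, 12.9-fold and 11.7-fold lower.

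Lists of cell division, matrix and inflammation genes were shifted up at 3 months by camera with its preset correlation. In the cell cycle list 7 of 17 genes rose and 0 fell, 11 when adjusted over the list alone (median 1.68, camera adjusted p = 1.82e-08, adjusted p = 0.252 with an estimated correlation). Among them were the replication helicase genes Mcm6 (2.34 ± 0.2), Mcm5 (2.55 ± 0.27) and Mcm2 (1.96 ± 0.24) and the mitotic regulator Cdc20 (1.63 ± 0.24). Extracellular matrix genes followed, with 8 of 22 higher and 12 adjusted over the list alone (median 1.01, camera adjusted p = 6.22e-08, adjusted p = 0.434 with an estimated correlation). They were led by the collagen genes Col1a1 (2.86 ± 0.38), Col4a2 (1.13 ± 0.17), Col3a1 (2.1 ± 0.34) and Col6a1 (1.5 ± 0.25). Among cytokine, chemokine and adhesion genes 6 of 21 rose, 11 adjusted over the list alone (median 1.5, camera adjusted p = 2.92e-07, adjusted p = 0.476 with an estimated correlation). They included Tnfaip3, a brake on NF-kB (2.18 ± 0.2), the T cell chemoattractants Cxcl9 (2.2 ± 0.27) and Cxcl10 (2.79 ± 0.4), and the adhesion molecule Vcam1 (2.05 ± 0.36). The interferon list was shifted up (median 0.95, camera adjusted p = 6.3e-06, adjusted p = 0.476 with an estimated correlation). In it 2 of 24 genes passed, Gbp2 and Oasl2 (1.69 ± 0.35), and 8 adjusted over the list alone. The MHC class II list was shifted up (median 1.65, camera adjusted p = 0.000959, adjusted p = 0.476 with an estimated correlation). Of its 8 genes 0 passed by limma, and 6 did so adjusted over the list alone.

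Macrophage and Kupffer cell markers were shifted up at 3 months (median 1.48, camera adjusted p = 3.23e-05, adjusted p = 0.527 with an estimated correlation). Of 20 genes 1 passed, Itgax, a marker of inflammatory macrophages (2.45 ± 0.49, with 1 ND array near background). Markers of lipid-associated macrophages were also up, with 2 of 12 past and 6 adjusted over the list alone (median 1.21, camera adjusted p = 0.00138, adjusted p = 0.476 with an estimated correlation). Trem2, a lipid-sensing receptor, rose by 2.62 ± 0.34. Stellate cell markers were shifted up (median 0.8, camera adjusted p = 0.00115, adjusted p = 0.476 with an estimated correlation), with 1 of 12 past, Pdgfra (0.95 ± 0.2). Endothelial markers were shifted up as well (median 0.56, camera adjusted p = 0.00288, adjusted p = 0.476 with an estimated correlation), with 1 of 17 past, Lyve1 (2.28 ± 0.34). Hepatocyte markers were shifted down with 0 of 20 past (median -0.53, camera adjusted p = 0.00374, adjusted p = 0.434 with an estimated correlation). So were ribosomal protein genes (median -0.46, camera adjusted p = 0.000302, adjusted p = 0.575 with an estimated correlation), with 1 of 28 past, Rpl4 (-1.1 ± 0.22). The calls of those last 2 lists ended under quantile normalization and with the authors' value table, that of endothelial markers without ND 3 months replicate 1, and that of lipid-associated macrophage markers with probes well above background on all arrays.

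Fatty acid oxidation genes, including targets of the receptor PPARa, were shifted up at 3 months: 2 of 28 rose, 14 adjusted over the list alone, and 0 fell (median 0.68, camera adjusted p = 6.22e-08, adjusted p = 0.252 with an estimated correlation). Cyp4a10, a fatty acid hydroxylase, rose by 1.34 ± 0.2 and the thioesterase gene Acot2 by 2.32 ± 0.45. Lipid droplet and uptake genes were shifted up with 2 of 20 past and 3 adjusted over the list alone (median 0.85, camera adjusted p = 0.000959, adjusted p = 0.476 with an estimated correlation). These were Apoa4, an apolipoprotein (2.92 ± 0.45), and Vldlr, a lipoprotein receptor (1.96 ± 0.35). Cholesterol synthesis genes were shifted down with 0 of 24 past (median -0.53, camera adjusted p = 0.0143, adjusted p = 0.747 with an estimated correlation), a call that ended without ND replicate 2 or HFD replicate 1 of 3 months. Genes higher in female than in male liver were shifted up, with 6 of 14 higher and 1 lower, and 8 higher and 2 lower adjusted over the list alone (median 2.11, camera adjusted p = 0.000959, adjusted p = 0.468 with an estimated correlation). The 1 that fell was Cyp17a1, a steroid hydroxylase (-3.41 ± 0.5), and the call ended with probes well above background on all arrays. Male-biased genes were shifted down, with 2 of 15 lower and 8 adjusted over the list alone (median -1.55, camera adjusted p = 2.71e-05, adjusted p = 0.476 with an estimated correlation). The 2 were Elovl3, a fatty acid elongase (-2.92 ± 0.44), and Cyp7b1, an oxysterol hydroxylase (-1.9 ± 0.3).

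Altogether 1045 of 20165 tested features changed at 3 months by limma with Benjamini-Hochberg adjustment, 305 higher and 740 lower on HFD. Of these 520 carry a gene symbol (245 higher and 275 lower). Camera with its preset correlation called 16 of 33 lists, 12 up and 4 down, and with an estimated correlation 0 (2 at unadjusted p under 0.05). By contrast fry, which asks whether a list's genes move on balance in 1 direction, called 4. The gene count was 0 without either ND array of 3 months (3030 at unadjusted p under 0.05 without replicate 1 and 2514 without replicate 2), 485 without HFD 3 months replicate 1, and 2232 without either HFD array of 9 months. Leaving out 1 array kept the calls of Itgax, Pdgfra and Rpl4 in 2 of 8 cases. The count was 68 with no filter on dim probes, 3972 with array weights and 2780 from the 4 arrays of 3 months alone.

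After 9 months the same question was asked for long feeding. Cyp2b13 was again the most raised gene (6.97 ± 1.18, 125-fold), and its relative Cyp2b10 rose by 4.35 ± 0.86. Cidea, a lipid droplet protein typical of brown fat and fatty liver, rose by 6.32 ± 1.27, Ubd by 4.96 ± 0.35 and Thrsp, a promoter of fatty acid synthesis, by 4.64 ± 1.02. With 1 array left out Cidea ran from 4.27 to 8.37, past the threshold in 1 of 8 cases, Cyp2b10 from 3.12 to 5.58 (1 of 8), Thrsp from 3.01 to 6.28 (2 of 8) and Cyp2b13 from 5.74 to 8.20 (6 of 8). Trem2 rose by 4.41 ± 0.34, Adgrv1, an adhesion receptor, by 4.49 ± 0.36 and Osbpl3, an oxysterol-binding protein, by 4.28 ± 0.49. The largest falls were those of Krtap19-5 (-5.1 ± 0.54), Dcaf12l2 (-5.01 ± 0.43), Baiap2l2 (-4.99 ± 0.53), Teddm2 (-4.53 ± 0.65), Ssbp2 (-4.52 ± 0.37), Olfr1350 (-4.26 ± 0.75), Sun5 (-3.87 ± 0.68) and Pramel34 (-3.76 ± 0.46). The other probes of Dcaf12l2, Teddm2 and Pramel34 were on average higher on HFD, by 0.89, 0.59 and 2.82, and those of Ssbp2 lower, at -2.38. As bounds, Gprc5b, Timp1 (an inhibitor of matrix proteases) and Vsig8 were at least 12.3-fold, 10.9-fold and 10.6-fold higher on HFD. Uncx, Gucy2c and Bhlha9 were at least 16.1-fold, 15.4-fold and 12.3-fold lower.

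Markers of lipid-associated macrophages had the smallest camera p of all lists at 9 months: 7 of 12 rose, 10 adjusted over the list alone, and 0 fell (median 2.46, camera adjusted p = 5.03e-07, adjusted p = 0.473 with an estimated correlation). They included Trem2, the tetraspanin gene Cd63 (2.5 ± 0.31) and Itgax (3.49 ± 0.49). The wider macrophage and Kupffer cell list was not shifted, with 1 of 20 past and a median of 0.3 (camera adjusted p = 0.428), but without ND 9 months replicate 1 it was shifted up (median 1.19, camera adjusted p = 2.73e-05). Matrix genes rose, 10 of 22 and 13 adjusted over the list alone (median 1.14, camera adjusted p = 1.02e-05, adjusted p = 0.54 with an estimated correlation). Among them were Col1a1 at 3.34 ± 0.38, Col3a1 at 2.92 ± 0.34 and Col6a1 at 1.71 ± 0.25. Interferon genes were shifted up with 3 of 24 past and 10 adjusted over the list alone (median 1.34, camera adjusted p = 1.02e-05, adjusted p = 0.63 with an estimated correlation). They were Oasl2 (1.97 ± 0.35), Gbp2 (2.0 ± 0.36) and the antiviral gene Rsad2 (1.75 ± 0.38). Of 21 cytokine, chemokine and adhesion genes 4 rose and 1 fell, 10 and 1 adjusted over the list alone (median 0.95, camera adjusted p = 0.000427, adjusted p = 0.63 with an estimated correlation). Cxcl9 rose by 1.98 ± 0.27 and Cxcl10 by 2.22 ± 0.4, and Cxcl13, a B cell chemoattractant, fell (-5.87 ± 1.26, with 1 HFD array near background). Genes of the unfolded protein response were shifted up, 3 of 19 past and 12 higher and 1 lower adjusted over the list alone (median 0.72, camera adjusted p = 1.88e-05, adjusted p = 0.473 with an estimated correlation). They were the chaperone gene Hyou1 (1.1 ± 0.21), Chac1 (1.48 ± 0.33) and Trib3 (0.95 ± 0.21). Cell cycle genes stayed up, 5 of 17 past, with 9 higher and 1 lower adjusted over the list alone (median 1.1, camera adjusted p = 0.000675, adjusted p = 0.473 with an estimated correlation), and Mcm5 at 1.78 ± 0.27. The MHC class II list had 1 of 8 past, H2-DMb1 (1.99 ± 0.43), and 4 adjusted over the list alone (median 1.4, camera adjusted p = 0.0076, adjusted p = 0.63 with an estimated correlation). That call ended without HFD 9 months replicate 2. Without ND 9 months replicate 1 the median was 1.90 for cytokine genes, 2.21 for MHC class II genes and 0.67 for cell cycle genes.

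At 9 months 3 lists of lipid genes stood higher on HFD than on ND by camera with its preset correlation. This need not be a rise over time. From 3 to 9 months fatty acid synthesis genes had medians of -1.85 on ND and -1.11 on HFD, and Srebf1 stood at -4.37 and -2.47. Lipid droplet genes had medians of 0.34 and 0.3, and adipocyte genes of -0.32 and 0.87. Fatty acid synthesis genes were shifted up with 4 of 19 past and 5 adjusted over the list alone (median 0.68, camera adjusted p = 0.00674, adjusted p = 0.679 with an estimated correlation). They included Srebf1, their transcriptional activator (2.75 ± 0.27), Pklr, pyruvate kinase of liver (2.51 ± 0.4), and Thrsp. Lipid droplet genes rose, 3 of 20 and 7 adjusted over the list alone (median 1.16, camera adjusted p = 0.00345, adjusted p = 0.63 with an estimated correlation). These were Pparg, the adipogenic receptor (1.4 ± 0.17), Vldlr (2.73 ± 0.35) and Cidea. Both calls ended without HFD 9 months replicate 1. Genes typical of adipocytes rose, 3 of 7 and 5 adjusted over the list alone (median 2.89, camera adjusted p = 0.00286, adjusted p = 0.473 with an estimated correlation). The 3 were Car3, a carbonic anhydrase that hepatocytes also express (2.89 ± 0.17), Fabp4, a fatty acid carrier (3.24 ± 0.46), and Cidea. Clock genes were shifted up with 3 of 16 higher and 1 lower, 7 and 1 adjusted over the list alone (median 0.83, camera adjusted p = 0.00972, adjusted p = 0.63 with an estimated correlation). The call ended without ND 9 months replicate 1 or HFD 9 months replicate 1. Dbp, an output of the clock, was at 2.76 ± 0.23 and Arntl, its core activator, at -1.75 ± 0.26. From 3 to 9 months the clock list had medians of -0.56 on ND and -0.33 on HFD. Fatty acid oxidation genes were not shifted (median -0.08, camera adjusted p = 0.218). Even so Acot1 (-1.76 ± 0.21), Ehhadh, a peroxisomal oxidation enzyme (-1.33 ± 0.18), and Cyp4a10 (-1.05 ± 0.2) were lower on HFD than on ND and Hadh (0.82 ± 0.19) was higher. The lower values need not be a fall over time: from 3 to 9 months the list had medians of 0.79 on ND and -0.02 on HFD. With 1 array left out Hadh never passed and Cyp4a10 passed in 1 of 8 cases. Female-biased genes stayed up, 4 of 14 past, 5 higher and 1 lower adjusted over the list alone (median 1.2, camera adjusted p = 0.00787, adjusted p = 0.54 with an estimated correlation). Male-biased genes stayed down (median -1.02, camera adjusted p = 0.0164, adjusted p = 0.679 with an estimated correlation), with 1 of 15 past, Elovl3 (-2.71 ± 0.44). These 2 calls ended without HFD 9 months replicate 1, the first also with no filter on dim probes and with probes well above background on all arrays, and the second without ND 9 months replicate 2. Stellate cell markers were up, 2 of 12 past (median 0.94, camera adjusted p = 0.00345, adjusted p = 0.63 with an estimated correlation), and so were endothelial markers, 1 of 17 (median 0.65, camera adjusted p = 0.0216, adjusted p = 0.63 with an estimated correlation). Hepatocyte markers were down with 0 of 20 past (median -0.33, camera adjusted p = 0.0341, adjusted p = 0.54 with an estimated correlation). These 3 calls ended without HFD 9 months replicate 1. The endothelial call ended in 4 of 19 settings in all and the hepatocyte call in 5 of 19.

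At 9 months 1670 of 20165 features changed, 717 higher and 953 lower on HFD, and 953 in all carry a symbol (567 higher and 386 lower). Camera called 16 of 33 lists, 14 up and 2 down, against 0 with an estimated correlation (3 at unadjusted p under 0.05) and 5 by fry. Which direction prevailed depends on the filter: probes well above background on all arrays gave 763 higher and 734 lower. Array weights gave 67 and 209. From the 4 arrays of 9 months alone limma called 0 genes (3907 at unadjusted p under 0.05), so the calls rest on the spread of all 8 arrays. The count was 487 without either ND array of 3 months, 867 and 365 without ND 9 months replicate 1 and 2 and 274 with no filter on dim probes. List calls numbered 8 without HFD 9 months replicate 1. Leaving out 1 array kept the calls of Chac1, Cxcl13, H2-DMb1 and Rsad2 in 1 of 8 cases and those of Olfr1350 and Trib3 in 2. Chosen after seeing the data, a fit of 6 arrays called 2270 genes without the pair of 9-month arrays that stood apart, ND replicate 1 and HFD replicate 2, of which 979 were called the same way from all 8 arrays.

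**Figure D1:**
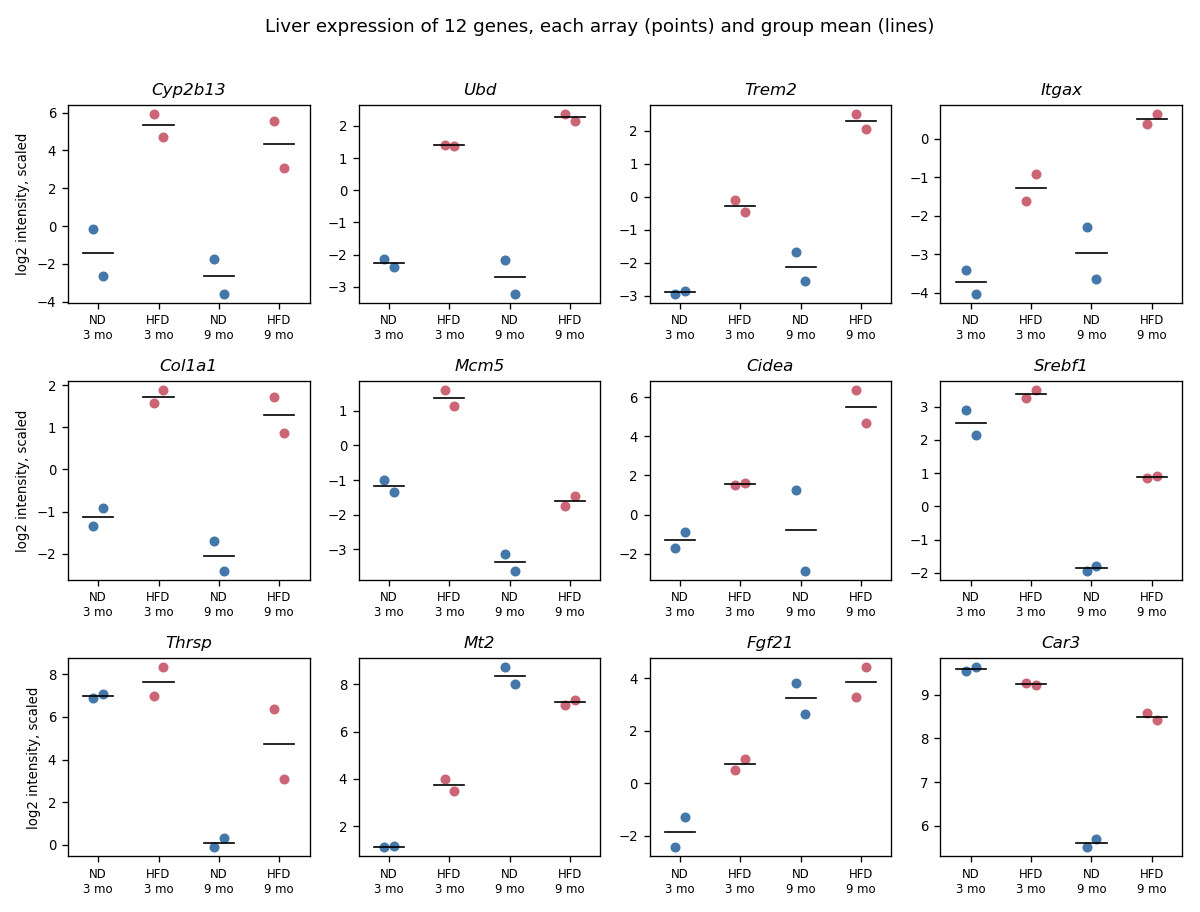
Scaled log2 intensity of 12 genes on each array (points, n = 2 animals per group) with group means (lines), by diet and months of feeding. Cyp2b13, Ubd, Trem2, Itgax and Col1a1 were higher on HFD at both durations, with log2 fold changes at 9 months of 6.97, 4.96, 4.41, 3.49 and 3.34.

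**Figure D2:**
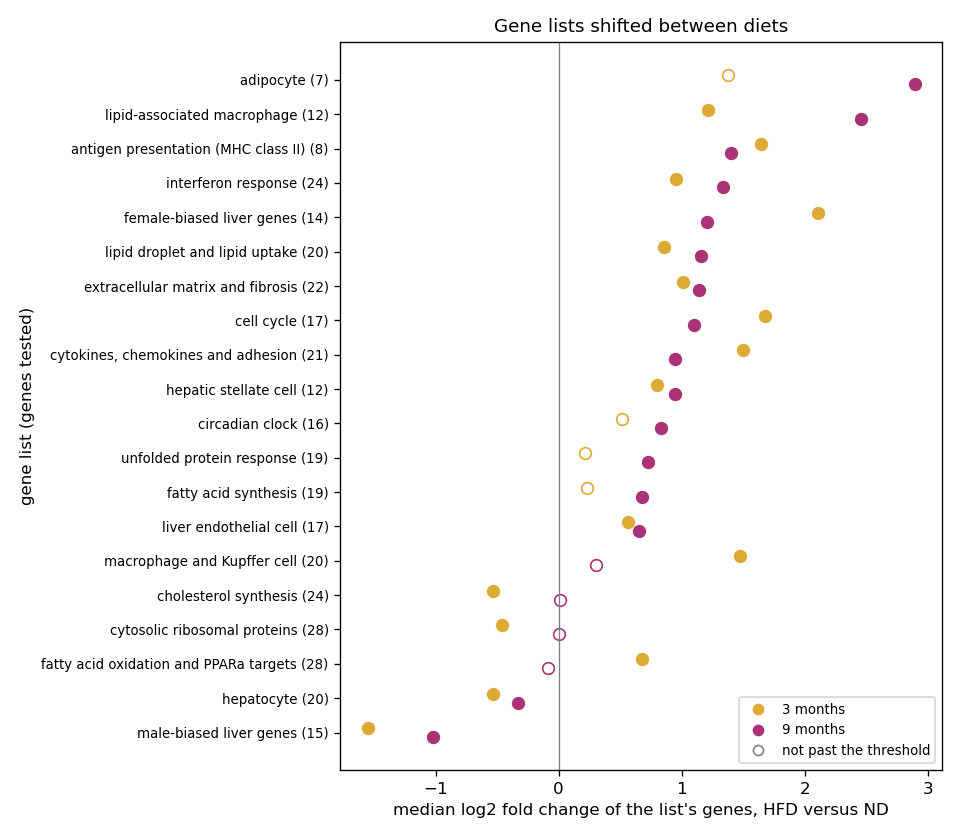
Median log2 fold change, HFD versus ND, of each gene list called by camera at 3 or 9 months, with the number of genes tested in parentheses; filled points passed the threshold. Lipid-associated macrophage markers stood at 1.21 at 3 months and 2.46 at 9 months, and male-biased genes at -1.55 and -1.02.

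A panel of 26 genes of inflammation, fibrosis and lipid metabolism was chosen for description whether or not it passed. Of these 24 were tested: Tnf was not well above background and Cd68 had no named probe. At 3 months 3 rose, Itgax, Col1a1 and Timp1 (at least 4.89-fold), and at 9 months 6, these and Pparg, Cidea and Srebf1. None fell. The chemokine gene Ccl2 stood at 2.94 ± 0.8 at 3 months (adjusted p = 0.0846) and 3.01 ± 0.8 at 9 months (adjusted p = 0.0694). The other inflammatory genes did not pass. Il1b was at 0.72 ± 0.87 and -0.38 ± 0.87 and Adgre1, the macrophage marker F4/80, at 1.72 ± 0.74 and 0.03 ± 0.74. Of acute-phase genes Saa1 was at 1.31 ± 1.43 and -0.58 ± 1.43 and Lcn2 at 3.1 ± 0.96 and 0.17 ± 0.96. Tgfb1, a profibrotic cytokine, was at 0.76 ± 0.4 and 0.21 ± 0.4 and Acta2, smooth muscle actin, at 0.61 ± 0.39 and 0.8 ± 0.39. Among lipid genes below the threshold were the fatty acid transporter Cd36 (1.59 ± 0.48 and 1.75 ± 0.48), Cidec (1.94 ± 0.78 and 1.64 ± 0.78) and Plin2 (0.79 ± 0.3 and -0.13 ± 0.3). Fasn, fatty acid synthase, was at 0.39 ± 1.02 and 0.98 ± 1.02 and Scd1, a desaturase, at -0.44 ± 0.76 and 1.73 ± 0.76. Cpt1a, which admits fatty acids to mitochondria, was at 1.31 ± 0.29 and -0.11 ± 0.29, Cyp4a14 at 1.06 ± 0.32 and -0.53 ± 0.32 and Fgf21, a fasting hormone, at 2.59 ± 0.59 and 0.61 ± 0.59. At 3 months Pparg stood at -0.11 ± 0.17, Cidea at 2.84 ± 1.27 and Srebf1 at 0.85 ± 0.27, below the threshold. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, and Pck1, of gluconeogenesis, were at -0.05 ± 0.8 and 0.2 ± 0.27 at 3 months and at -1.03 ± 0.8 and -1.12 ± 0.27 at 9 months. Another 1 of the panel is not described here.

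Averaged over both durations, Cyp2b13 (6.86 ± 0.77), Cidea (4.58 ± 1.05), Ubd (4.31 ± 0.33), Slc22a29 (3.82 ± 0.35) and Cyp2b10 (3.82 ± 0.6) rose most on HFD (n = 4 animals per diet). Pax2 (-4.78 ± 0.7), Krtap19-5 (-4.76 ± 0.38), Teddm2 (-4.37 ± 0.43), Olfr1350 (-4.15 ± 0.49) and Tox4 (-4.15 ± 0.83) fell most. Ccl2 (2.97 ± 0.52), Cd36 (1.67 ± 0.32) and Cidec (1.79 ± 0.51) passed the threshold in this comparison. With duration as a covariate, 4453 of 20165 features changed, 2069 higher and 2384 lower. Which direction prevailed depends on the processing: the authors' value table gave 2643 higher and 2149 lower, normexp 2361 and 2044, and probes well above background on all arrays 1940 and 1728. Of the 4453, 2680 carry a symbol (1685 higher and 995 lower). Of the features called at each duration, 166 were higher and 437 lower at both, and 3 were called in opposite directions. Independent calls would share 10.8 and 34.97. Both comparisons take each gene's spread from the same fit and set the same 2 slides against each other, so their calls could not be independent. The diet effects at 3 and 9 months, which share no array, correlated across all tested features with r = 0.684 (Spearman's rho = 0.640). The highest |r| of the 8 other exchanges of arrays between diets within each duration was 0.356. A difference between the slides would recur at both durations and could raise r and the overlap. Genes that rose and have other probes detected somewhere on the arrays had them higher too in 339 of 425 cases (79.8%, exact 95% interval 75.6 to 83.5%). Genes that fell had them lower in 163 of 242 (67.4%, 61.1 to 73.2%). With undetected probes counted as well, the shares were 81.9% of 515 and 46.9% of 356. The count was 2386 with no filter on dim probes, 2391 when a 2-fold change was asked, 2073 and 1840 without ND 3 months replicate 1 and 2, 2376 without ND 9 months replicate 2 and 2795 without HFD 3 months replicate 1.

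**Figure D3:**
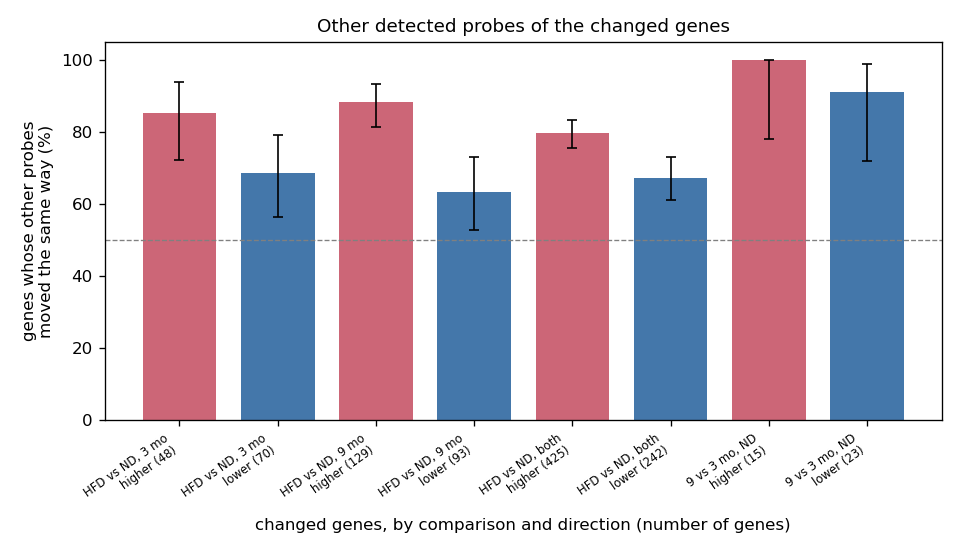
Percent of changed genes with a symbol whose other detected probes moved on average in the same direction, by comparison and direction, with exact binomial 95% intervals and the number of genes in parentheses; the dashed line marks 50%. For genes changed on HFD over both durations the share was 79.8% for rises and 67.4% for falls.

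Whether the diet effect differed between 9 and 3 months was tested directly as an interaction. No gene passed. The smallest p-values were those of Car3, whose diet effect was 3.24 ± 0.24 greater at 9 months (adjusted p = 0.146), Wfdc13 (-3.11 ± 0.29), the fatty acid hydroxylase gene Cyp4a32 (-2.83 ± 0.3), Rab30 (-2.59 ± 0.28) and Mt2, a metal-binding metallothionein (-3.73 ± 0.42). The other probe of Rab30 stood at 0.27. Chosen after their values were seen, Cidea (3.48 ± 1.8, adjusted p = 0.713), Trem2 (1.79 ± 0.48, 0.494) and Srebf1 (1.9 ± 0.38, 0.372) did not pass either. By camera, in a test of lists that was not planned for the interaction, 13 of 33 lists differed. The effect was lower at 9 months in fatty acid oxidation genes, with 0 of 28 past and 9 lower adjusted over the list alone (median -0.71, camera adjusted p = 6.11e-14, adjusted p = 0.17 with an estimated correlation). From 3 to 9 months these genes had medians of 0.79 on ND and -0.02 on HFD, so the difference lay mostly in the ND arrays. The diet effect was lower too in cell cycle genes (median -0.61, camera adjusted p = 0.000194, adjusted p = 0.35 with an estimated correlation) and macrophage and Kupffer cell markers (median -1.03, camera adjusted p = 0.000576, adjusted p = 0.867 with an estimated correlation). It was greater at 9 months in lipid-associated macrophage markers (median 1.06, camera adjusted p = 9.22e-05, adjusted p = 0.582 with an estimated correlation) and unfolded protein response genes (median 0.7, camera adjusted p = 5.97e-05, adjusted p = 0.382 with an estimated correlation). The same held for adipocyte genes (median 1.34, camera adjusted p = 0.00351, adjusted p = 0.35 with an estimated correlation). In cholesterol synthesis genes the difference was positive too (median 0.89, camera adjusted p = 0.00096, adjusted p = 0.867 with an estimated correlation). There the effect was weaker at 9 months, with medians of -0.53 at 3 months and 0.007 at 9 months. For macrophage markers the call ended without ND 9 months replicate 1 (camera adjusted p = 0.415) or HFD 9 months replicate 1, for cholesterol genes without HFD replicate 1 of either duration, and for adipocyte genes with no filter on dim probes. By limma 0 of 20165 features differed (1537 at unadjusted p under 0.05, 1008 expected by chance), and other settings gave 0 to 3. With an estimated correlation 0 lists passed (4 at unadjusted p under 0.05) and by fry 2, fatty acid oxidation and adipocyte genes.

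The comparison of 9 with 3 months on ND covers months on the normal diet, age and row of the slide, which changed together. Metallothionein genes rose most, Mt2 by 7.22 ± 0.3 (149-fold) and Mt1 by 5.91 ± 0.34, with Fgf21 (5.09 ± 0.59), the cell cycle inhibitor Cdkn1a (4.06 ± 0.33) and Rad51b (3.72 ± 0.39). The other probe of Cdkn1a stood at 0.046. The largest falls were those of Thrsp (-6.89 ± 1.02), Srebf1 (-4.37 ± 0.27), Car3 (-3.98 ± 0.17), Inmt, a methyltransferase (-3.68 ± 0.35), and Msmo1, a sterol synthesis enzyme (-3.66 ± 0.5). As bounds, Irak3, Glt8d2 and Slc6a21 were at least 9.44-fold, 7.23-fold and 7.04-fold higher at 9 months. Adgrf1 and Sh2d4a were at least 19.4-fold and 3.26-fold lower. List members named from here on were chosen by their p-values after these were seen. Cholesterol synthesis genes fell as a list, 4 of 24 and 21 adjusted over the list alone (median -2.29, camera adjusted p = 1.75e-15, adjusted p = 0.579 with an estimated correlation). Among them were Mvk (-2.58 ± 0.3) and Insig1 (-3.03 ± 0.46). Fatty acid synthesis genes fell, 2 of 19 and 10 adjusted over the list alone (median -1.85, camera adjusted p = 1.44e-08, adjusted p = 0.579 with an estimated correlation). Fatty acid oxidation genes rose, 6 of 28 and 16 adjusted over the list alone (median 0.79, camera adjusted p = 4.76e-15, adjusted p = 0.134 with an estimated correlation). They included Cyp4a10 (2.94 ± 0.2), Acot1 (3.04 ± 0.21), Ehhadh (2.05 ± 0.18) and Cyp4a14 (2.75 ± 0.32). Macrophage markers were shifted up with 0 of 20 past and 2 adjusted over the list alone (median 1.59, camera adjusted p = 1.48e-09, adjusted p = 0.579 with an estimated correlation). So were cytokine genes with 2 of 21, 7 higher and 2 lower adjusted over the list alone (median 1.05, camera adjusted p = 3.87e-06, adjusted p = 0.579 with an estimated correlation). In these 2 lists ND 9 months replicate 1 stood above replicate 2 by a median of 1.74 and 1.13, and without it their medians were 0.71 and 0.33, and interferon genes were shifted down (-0.45, camera adjusted p = 0.014). Respiratory chain genes were shifted down with 0 of 27 past (median -0.43, camera adjusted p = 4.15e-06, adjusted p = 0.134 with an estimated correlation). Xenobiotic metabolism genes were down with 2 of 19 past (median -0.98, camera adjusted p = 0.00601, adjusted p = 0.579 with an estimated correlation) and male-biased genes with 0 of 15 (median -0.6, camera adjusted p = 0.00247, adjusted p = 0.674 with an estimated correlation), the latter at -0.32 without ND 9 months replicate 1. Cell cycle genes were down (median -0.78, camera adjusted p = 0.0186, adjusted p = 0.579 with an estimated correlation), with 1 of 17 lower, Mcm5 (-2.2 ± 0.27), and 1 higher, Cdkn1a. Smaller shifts up were seen in markers of T and NK cells (median 0.33, camera adjusted p = 0.0122, adjusted p = 0.726 with an estimated correlation) and dendritic cells (median 0.58, camera adjusted p = 0.0395, adjusted p = 0.579 with an estimated correlation). Acute-phase genes were up too (median 0.31, camera adjusted p = 0.0152, adjusted p = 0.726 with an estimated correlation), and 0 genes of these 3 lists passed by limma. The dendritic cell call ended in 12 of 18 settings. The acute-phase call ended only without ND 9 months replicate 1, and the T and NK cell and cell cycle calls ended there and in other settings. Outside the called lists, the clock genes Dbp (-2.83 ± 0.23) and Bhlhe40 (-2.46 ± 0.32) fell and Arntl (2.02 ± 0.26) rose.

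On ND 209 of 20165 features changed with duration, 89 higher and 120 lower. Of these 152 carry a symbol (60 higher and 92 lower). Genes that rose had other detected probes that were higher in 15 of 15 cases, and genes that fell had them lower in 21 of 23. With undetected probes counted, the median of the other probes was 0.61 for rises, against 2.31 for the probes used. For falls it was -1.82, against -1.96. Camera called 12 lists, 6 up and 6 down, against 0 with an estimated correlation (2 at unadjusted p under 0.05) and 3 by fry. Scaling to the detected probes alone shifted the median of all genes by 0.141 and gave 94 higher and 64 lower, so which direction prevailed depends on the scaling. Rises also prevailed with a replicate block (36 and 20). The count was 0 without either ND array of 3 months (1671 and 1463 at unadjusted p under 0.05 without replicate 1 and 2), 4 and 27 without ND 9 months replicate 1 and 2, 68 without either HFD array of 3 months and 340 without either of 9 months. Leaving out 1 array kept the calls of Arntl, Bhlhe40, Cyp4a14, Fgf21, Insig1, Mcm5, Msmo1, Mvk, Rad51b and Thrsp in 2 of 8 cases. The count was 5 with no filter on dim probes, 324 with trend and robust moderation, 1409 with array weights, 56 with a replicate block and 137 from its 4 arrays alone.

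**Figure D4:**
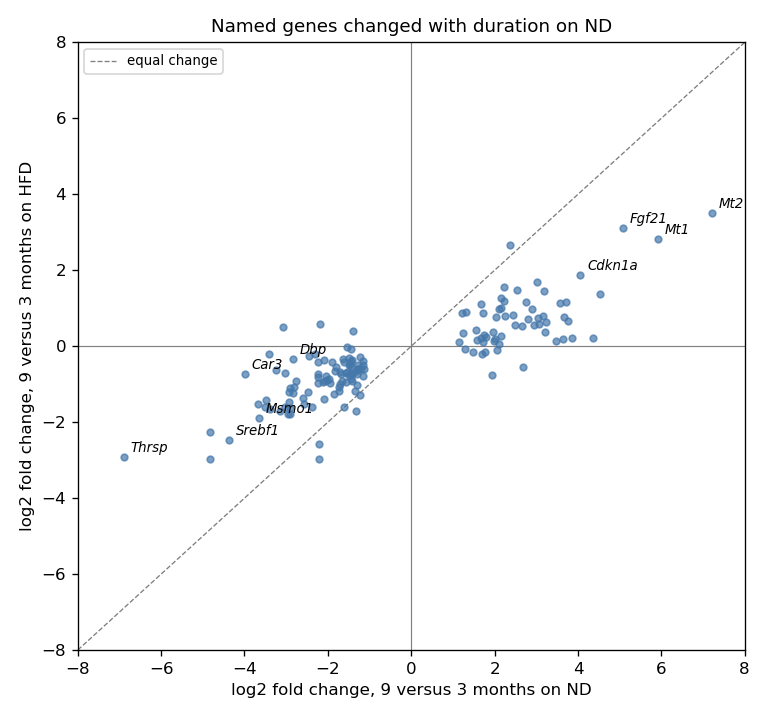
Log2 fold change at 9 versus 3 months on ND (x axis) and on HFD (y axis) of the 152 genes with a symbol that changed on ND; the dashed line marks equal change. On HFD 142 of the 152 moved in the same direction, with a median of 0.76 against 2.11 on ND.

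On HFD the same comparison of 9 with 3 months called 2 features, 1 higher and 1 lower (3120 at unadjusted p under 0.05). The lower one was Wfdc13, a protein with a whey acidic protein domain (-3.53 ± 0.21, adjusted p = 0.0306, 1 of the 9-month arrays near background), which lies outside the rule for names and was named after its value was seen. Next came Mt2 (3.5 ± 0.3), Mcm6 (-2.29 ± 0.2), Mcm5 (-2.97 ± 0.27) and Tuba8, a tubulin (2.79 ± 0.28), each with an adjusted p of 0.0555. Cholesterol synthesis genes were shifted down, with 0 of 24 past and 13 adjusted over the list alone (median -1.57, camera adjusted p = 2.91e-09, adjusted p = 0.81 with an estimated correlation). So were cell cycle genes, 9 lower and 1 higher adjusted over the list alone (median -1.39, camera adjusted p = 1.53e-06, adjusted p = 0.477 with an estimated correlation). Fatty acid synthesis genes (median -1.11, camera adjusted p = 2.87e-05, adjusted p = 0.824 with an estimated correlation) and respiratory chain genes (median -0.22, camera adjusted p = 0.0491, adjusted p = 0.677 with an estimated correlation) were also down. Lipid-associated macrophage markers were shifted up, 8 of 12 adjusted over the list alone (median 1.59, camera adjusted p = 7.97e-06, adjusted p = 0.677 with an estimated correlation). Trem2, chosen after its value was seen, stood at 2.56 ± 0.34. Smaller shifts up were those of unfolded protein response genes (median 0.47, camera adjusted p = 0.00404, adjusted p = 0.677 with an estimated correlation) and cytokine genes (median 0.68, camera adjusted p = 0.00814, adjusted p = 0.824 with an estimated correlation). The same was seen for ribosomal protein genes (median 0.24, camera adjusted p = 0.0139, adjusted p = 0.824 with an estimated correlation) and macrophage markers (median 0.57, camera adjusted p = 0.0222, adjusted p = 0.824 with an estimated correlation). Camera called 9 lists, against 0 with an estimated correlation (1 at unadjusted p under 0.05) and 1 by fry. The gene count was 1933 without HFD 9 months replicate 1, 18 without replicate 2, 1 without HFD 3 months replicate 2 and 0 by limma without any 1 ND array (2041 to 2951 at unadjusted p under 0.05). The respiratory chain call ended in 12 of 19 settings, the ribosomal call in 6 and the macrophage call in 5. Without HFD 3 months replicate 2 the fatty acid synthesis and unfolded protein response calls ended, and without HFD 9 months replicate 1 the latter and the cytokine call. Without HFD 9 months replicate 2 lipid droplet, NRF2 and interferon genes passed upward and male-biased genes and T and NK cell markers downward. Other settings gave 0 to 69 genes.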

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

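The tests of slide position and hepatocyte share, and all alternatives for the lists of the interaction, were chosen only after the results were seen. The diet effect differed between 9 and 3 months by camera in 13 lists, given here as the median difference on the log2 scale. The main test of these lists was not planned either. The difference was positive in adipocyte genes (1.338), lipid-associated macrophage markers (1.056), cholesterol synthesis (0.893), unfolded protein response (0.702), fatty acid synthesis (0.594), male-biased (0.517), ribosomal protein (0.401) and respiratory chain genes (0.276). A positive difference is not always a stronger effect. Cholesterol synthesis genes had medians of -0.53 at 3 months and 0.007 at 9 months, and male-biased genes of -1.55 and -1.02. Ribosomal protein genes had medians of -0.46 and 0.006, and respiratory chain genes of -0.15 and 0.008. The difference was negative in macrophage and Kupffer cell markers (-1.033), fatty acid oxidation genes (-0.708), cell cycle genes (-0.607), T and NK cell markers (-0.423) and cytokine, chemokine and adhesion genes (-0.22). For the 6 of these not described above, the adjusted p was 0.0341 for fatty acid synthesis, 0.0462 for male-biased, 0.00012 for ribosomal protein, 0.0455 for respiratory chain and cytokine genes and 0.00508 for T and NK cell markers. With an estimated correlation it was 0.51 for respiratory chain genes and 0.867 for each of the other 5. Calls ended in 15 of 19 settings for cytokine genes, 14 for respiratory chain, 11 for male-biased, 7 for fatty acid synthesis, 6 for T and NK cell and 1 for ribosomal protein genes. Outside the main measurement, 3 of 96 control probes of another spike-in set were well above background on all arrays, and no explanation was tested.

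Between 9 and 3 months on ND 152 named genes changed, which is 1 arm of the interaction. On HFD, whose arrays held the same places on the other slide, 142 of them moved in the same direction, by a median of 0.76 (95% interval of a bootstrap over genes, here and below, 0.68 to 0.88) against 2.11 on ND. The ND median is raised because the genes were picked on it, so position on the slide, with an equal effect on both slides, was tested again on 152 genes picked from 1 ND pair of arrays. The other ND pair gave medians of 2.42 (picked on replicate 1) and 2.81 (picked on replicate 2), and HFD 1.11 (0.88 to 1.36) and 1.15 (0.84 to 1.42). These intervals reach 0.5 of the ND medians, the bound set for this test, so position stays open. A longer time without food before collection could raise fasting genes, and 13 such genes outside the lists had a median of 0.45 (-0.25 to 0.60) with 0 past the threshold by limma, which leaves it open. Another time of day could move the clock: 3 clock-driven genes outside the list had a median of -0.99 that met the bound set beforehand, but the interval spans 0 (-1.95 to 1.14), 0 genes passed by limma, and Lonrf3 (1.14 ± 0.41) moved against Wee1 (-1.95 ± 0.32) and Usp2 (-0.99 ± 0.68). Age and months on the diet, which the design names, remain open and untested.

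In ND 9 months replicate 1 immune and acute-phase genes stood above replicate 2, with median log2 differences of 1.74 for macrophage markers, 1.49 for MHC class II, 1.13 for cytokine genes and 0.75 for acute-phase genes. Lipid droplet and uptake genes stood above it too, by 0.78. A shift of that whole array by its scaling is argued against, since 48 hepatocyte and ribosomal protein genes differed by a median of 0.036 (-0.031 to 0.069). The test does not cover a difference confined to dim spots, which stays open. Scaled negative controls stood at -5.68 on replicate 1 and -6.42 on replicate 2, and 45.0% and 54.1% of spots were well above background. A lower share of hepatocytes is argued against only as the whole cause, by a bound set after the results were seen. The 44 genes of 4 other cell types differed by 0.21 (0.05 to 0.36), against 1.74 for macrophage markers. Of stellate markers 12 of 12 and of endothelial markers 14 of 17 were higher in replicate 1, but only 1 of 8 cholangiocyte and 3 of 7 erythroid markers. A lower share may therefore contribute. An acute-phase response in 1 animal may contribute, but 5 acute-phase genes outside the list had a median of 0.091 (-0.193 to 0.923), which leaves it open. Without this array the difference of the diet effect was -0.19 for macrophage markers (adjusted p = 0.415) and 0.25 for cytokine genes (adjusted p = 0.506), while it stayed past the threshold for lipid-associated macrophage markers (1.58), adipocyte genes (1.57) and fatty acid oxidation genes (-0.64). Without it the difference also passed for interferon genes (0.60, adjusted p = 0.000704) and MHC class II genes (0.67, adjusted p = 0.0304).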

How the results depend on the processing

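Scaling to detected probes, the 6 arrays left when the pair that stood apart is dropped, and all settings for the lists of the interaction were chosen after seeing the data. Unless said otherwise the cause was not tested. Genes given only as bounds were not followed except Timp1, whose call was kept at 3 months in 8 of 11 other settings and in 4 of 8 cases without 1 array, and at 9 months in 11 of 12 and 7 of 8. Of Timp1 and the genes named with a value, none past the threshold changed direction in any setting run, leaving out arrays included: of 1690 values of such genes under other settings 1403 kept their side of the threshold and 287 lost it, and of 1096 without 1 array 662 kept it and 434 lost it. Genes named by size were picked for no overlap between the arrays compared, so leaving out 1 array could not turn their direction.

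Counts of changed genes that moved by more than 1.5 times were these, where 0 refers to limma. Quantile normalization gave 1 for the interaction and 61 for duration on HFD, normexp 32 for duration on HFD, and the values of the authors' own table gave 69 for duration on HFD and 7 lists for the interaction. With no filter on dim probes, diet at 3 months gave 68, at 9 months 274, averaged 2386, duration on ND 5 and on HFD 0 (2822 at unadjusted p under 0.05), and the diet effects correlated with r = 0.622 across genes. Probes well above background on all arrays gave 1 for the interaction and 16 for duration on HFD, a floor on dim values 2 and 57, and trend and robust moderation 1 and 19, with 324 for duration on ND. Array weights gave 3972 for diet at 3 months, 276 at 9 months, 1409 for duration on ND and 0 on HFD (1782 unadjusted). A replicate block gave 56 for duration on ND and 0 on HFD (3148 unadjusted). The 4 compared arrays alone, with fewer degrees of freedom, gave 2780 for diet at 3 months, 0 at 9 months (3907 unadjusted), 137 for duration on ND and 0 on HFD (1718 unadjusted). A 2-fold minimum, which removes smaller changes by construction, gave 2391 for diet averaged. Camera with an estimated correlation called 0 lists in each of the 5 comparisons (unadjusted 2 and 3 for diet at 3 and 9 months, 2 and 1 for duration on ND and HFD, 4 for the interaction), and fry 4, 5, 3, 1 and 2 in that order.

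Leaving out 1 array gave 0 to 2232 genes for diet at 3 months, 365 to 2505 at 9 months, 1840 to 5949 averaged, 0 to 3 for the interaction, 0 to 340 for duration on ND and 0 to 1933 on HFD. The lists numbered 15 to 19 for diet at 3 months, 8 to 17 at 9 months, 9 to 19 for duration on ND, 6 to 11 on HFD and 7 to 18 for the interaction, and r ran from 0.543 to 0.704. A group of 1 array was assumed to vary like the others. A slide term could not be fitted for diet.

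The genes that turned sign were below the threshold. Under normexp and the authors' value table these were Cyp7a1 at 3 months (0.048 and 0.103) and Adgre1 at 9 months (-0.087 and -0.025, with -0.307 for the mean of all kept probes and -0.015 for scaling to detected probes). Plin2 at 9 months turned under quantile normalization (0.073). From 6 arrays at 9 months Il1b (0.10), Saa1 (1.56), Plin2 (0.29) and Cpt1a (0.40) turned. Without 1 array the lowest and highest values of genes that turned were these. At 3 months they were -1.02 and 0.91 for Cyp7a1, -1.25 and 2.02 for Fasn, -1.32 and 0.44 for Scd1. At 9 months they were -1.11 and 1.17 for Adgre1, -0.46 and 0.24 for Cpt1a, -1.61 and 0.85 for Il1b, -1.44 and 1.77 for Lcn2, -0.54 and 0.29 for Plin2, -3.01 and 1.85 for Saa1, -0.33 and 0.76 for Tgfb1. Signal over background limits the values of dim genes, and 40.6% to 54.1% of spots exceeded it.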

Other observations

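The tests of other probes, gene families and slides were chosen only after the results were seen. The list of xenobiotic metabolism genes was not shifted by diet (medians -0.13 and 0.05 at 3 and 9 months with means of 0.29 and 0.88, camera adjusted p = 0.61 and 0.493), but single genes differed. Nr1i3, the nuclear receptor CAR, which activates Cyp2b genes, rose by 1.46 ± 0.22 at 3 months, and Cyp2c29 (-1.11 ± 0.2), Gstp1 (-1.93 ± 0.37) and the growth factor gene Igf1 (-1.28 ± 0.21) fell. The metallothionein genes Mt1 (2.0 ± 0.34) and Mt2 (2.6 ± 0.3) rose at 3 months. At 9 months Gsta1, a glutathione transferase, rose by 3.47 ± 0.73, while the bile acid genes Cyp8b1 (-2.21 ± 0.4) and Baat (-1.65 ± 0.34), the amino acid catabolic gene Tat (-1.84 ± 0.3) and the insulin signalling gene Irs2 (-1.42 ± 0.31) fell. With 1 array left out Irs2 never passed, Gsta1 passed in 1 of 8 cases and Baat in 2. The T cell coreceptor gene Cd4 fell at both durations (-2.24 ± 0.35 and -3.0 ± 0.35), while the list of T and NK cell markers was not shifted (medians 0.68 and -0.02, camera adjusted p = 0.142 and 0.547), with 1 of 16 higher and 1 lower at 3 months. Cd22, a B cell receptor (-1.61 ± 0.3), and Cftr, a chloride channel of bile ducts (-1.79 ± 0.29), fell at 9 months. The call of Cd22 was kept in 2 of 8 cases with 1 array left out.

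The lists that camera called in no comparison are given with their medians at 3 and 9 months of diet. Bile acid genes stood at -0.11 and -0.41, NRF2 and oxidative stress genes at 0.08 and 0.29, gluconeogenesis and insulin signalling genes at 0.09 and 0.02 (with means of -0.02 and -0.35), B and plasma cell markers at 0.77 and 0.55, and neutrophil markers at 0.81 and 1.04. Without ND 9 months replicate 1 B and plasma cell markers passed upward at 3 and 9 months (camera adjusted p = 0.00482 and 0.00958, with a median of 1.01 at 9 months), as did acute-phase genes at 9 months (0.59, camera adjusted p = 0.00673). Neutrophil markers at 9 months stood at 1.71 without that array and at -0.17 without HFD 9 months replicate 2, without passing. Cholangiocyte markers stood at 0.21 and -0.01, erythroid markers at 0.13 and 0.85 and pancreatic acinar markers at -0.45 and -0.24.

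The named genes that changed on HFD over both durations differed by direction. Of 159 tested genes of families named after smell and pheromone receptors, keratin-associated proteins, defensins and germ cell proteins, 46 were among the 995 lower genes (4.62%) and 4 among the 1685 higher ones (0.237%), against 1.23% of the genes tested (Fisher's exact test, odds ratio 5.05, p = 1.26e-15, genes not being independent). The families were chosen after the results were seen, with Krtap19-5, Olfr1350 and Pramel34 among the largest falls. The p-value is therefore no independent test. Signal of single probes alone is argued against as the whole cause in both directions: other detected probes moved the same way for 79.8% of higher genes (95% interval 75.6 to 83.5%) and 67.4% of lower ones (61.1 to 73.2%), against 50.6% for 781 genes with unadjusted p over 0.5, though with undetected probes counted the share for lower genes was 46.9%. A change may itself bring a probe above background, so other probes detected on the diet where the gene was lower were counted too. They moved the same way for 78.4% of 398 higher genes (74.0 to 82.3%) and 63.3% of 207 lower ones (56.3 to 69.9%). Signal of single probes may still lie behind part of the lower genes. A difference between the 2 slides could lie behind the lower genes, and 0 slides hold arrays of both diets, so slide and diet cannot be told apart.

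Of the 34 splits of the 8 arrays into 4 and 4 that could be fitted, 1, the real one, gave as many changed genes (4453 against at most 0 by limma in the others), a share of 1 in 34, the smallest these splits allow. The other splits leave the difference between diets in the spread, which can lower their counts, and the real split is also the split by slide. Only 18 splits keep 2 arrays of each duration on each side (at most 0 genes by limma in the others), too few for a share under 0.05.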
